A study of Mus musculus with 6 samples.

How the data were processed

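RNA was profiled by short-read sequencing in 6 libraries of transduced mouse LT-HSCs, 3 with an shRNA against Kat6b and 3 with a non-targeting control (NTC). Per the labels' protocols, cells were cultured in SFEMII medium with SCF (10 ng/ml), TPO (20 ng/ml), IGF2 (20 ng/ml) and FGF (10 ng/ml), infected at an MOI of 1000 and sorted as viable GFP-positive cells. Total RNA was extracted from the sorted cells. Complementary DNA was amplified by the Ribo-SPIA method of the Ovation RNA-seq V2 kit, made into libraries with the Kapa Hyper Prep kit and read as 75 bp single ends on a NextSeq 500. Amplification from few cells copies molecules many times, and no molecular identifiers are described, so counts are not independent molecules and floors cover counting error only. No label states that the kit or the counting kept the strand, so reads of overlapping antisense genes cannot be told apart.

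The deposited file holds counts per Ensembl gene, as whole numbers, which the authors made from the reads with no normalization that the file or labels record. The submitters' processing notes name RSEM 1.2.12, Bowtie2 2.2.0, SAMtools 0.1.18, edgeR 3.5.3 and the build GRCm38, without their roles. Whether the whole numbers are rounded RSEM estimates is not given in the sources used here, nor is the annotation release. Estimates of that kind share reads among near-identical genes, and values of paralogs and pseudogenes are uncertain for this reason. The table lists 38924 genes, 18213 of them at 0 in all libraries. Gene symbols, coordinates and 3' UTRs came from GENCODE M21, also on GRCm38, by exact match of the gene identifier, which named 37607 genes. The other 1317 took 0.283% to 0.316% of the counts of a library and stayed in the tests. Each column was tied to its sample by the column name that the sample's description gives.

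Library totals ranged from 13698300 to 18870736 counts. At these totals 3 counts over the Kat6b shRNA group correspond to 0.0674 CPM, which served as the floor for genes at 0 in that group. Chi-square statistics per degree of freedom between library pairs lay between 15.7 and 120, so no library differed from another by sampling noise alone and none was counted as a duplicate. The p-values measure the spread between these libraries.

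Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with robust dispersions. Library sizes were scaled with TMM factors, and filterByExpr kept 13612 genes. P-values were adjusted by the Benjamini-Hochberg method over these genes, at a threshold of 0.05. The biological coefficient of variation was 0.257. CPM values are scaled by the TMM factors, log2 fold changes are Kat6b shRNA over NTC, and intervals are at 95%. On counts simulated for the same comparison over 13612 genes, in 3 runs with 200 changed genes each, the test called 10.4% of genes changed 1.5-fold, 54.7% of those changed 2-fold and 84.3% of those changed 4-fold, and 24 of 322 calls were false. The real comparison called 6 genes. Fewer calls make the Benjamini-Hochberg cut stricter, so the simulated shares may be too high for it. Library measures were compared with exact two-sided permutation tests.

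Before the data were examined, the design, the named genes and 27 gene lists were fixed for stem cell identity, lineages, other cell types, stress, metabolism, chromatin and RNA quality. Lists with at least 5 tested members, 24 in all, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and adjusted over those 24. Camera with an estimated correlation and fry were alternatives. The named genes were Kat6b, then up to 12 genes in each direction with mean CPM of at least 5 and groups that did not overlap. Genes past the adjusted threshold came first, in order of fold change, and the places left were filled by the smallest unadjusted p and reported as values. From each list, up to 4 called members were named or, where none was called, the 2 of smallest p. Predicted genes without a name were left out of the names but not of the counts.

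The alternatives fixed in advance were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no filter, 10 counts in 3 libraries, 1 CPM in 6 libraries, the replicate number as a block, non-robust dispersions and each library left out in turn. A fit without genes of the mitochondrial genome and rRNA-like genes, and one without genes that carry either of 2 heptamers in the 3' UTR, were added after seeing the data.

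To look for short sequences that go with the fold changes, the longest annotated 3' UTR of each of 11951 tested genes was searched for each of 16119 heptamers held by at least 50 genes and missing from at least 50. For each heptamer, the ratio of log2 fold change to SE was regressed on its presence, with the dinucleotide composition and length of the UTR and the mean expression of the gene as covariates (Python 3.11.15, numpy 2.4.6, pandas 2.3.3). The t value of presence was set against the lowest t in 100 permutations over genes. Genes are not independent replicates, so the same regression was repeated on other splits of the libraries and without each library.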

Results

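Total RNA was measured in long-term haematopoietic stem cells (LT-HSCs), the rare bone marrow cells that maintain blood formation over the life of the animal. The cells came from the bone marrow of female C57/BL6J mice aged 2 to 4 months. They were infected with a lentivirus that carried either a short hairpin RNA (shRNA) against Kat6b or a non-targeting control hairpin (NTC), and infected cells were isolated by their GFP signal. Per the labels, each group held 3 independent biological replicates, and 1 hairpin against Kat6b was used. The time in culture before the sort is given as 36 hours in the growth protocol and as 2 days in the description of the series. Gene counts summed to 17705790, 18870736 and 18260847 in NTC replicates 1, 2 and 3. They summed to 13698300, 16050394 and 15862124 in Kat6b shRNA replicates 1, 2 and 3, so every Kat6b shRNA library was shallower than every NTC library (exact two-sided permutation test, p = 0.1, the smallest value 3 against 3 libraries allow). Between 16798 and 17682 genes had at least 1 count in a library. Genes of the mitochondrial genome took 32.5% of the counts in Kat6b shRNA replicate 1, against 24.2% and 20.4% in replicates 2 and 3 and 19.4% to 22.0% in the NTC libraries. The first principal component held 34.2% of the variance and set Kat6b shRNA replicate 1 apart from replicate 3, with the other 4 libraries between them. On the second, with 23.3%, the 3 NTC libraries (17.7 to 23.8) lay above the 3 Kat6b shRNA libraries (−43.1 to 8.18).

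The study makes 1 comparison, Kat6b shRNA against NTC. It asks which transcripts of LT-HSCs respond when Kat6b, a histone acetyltransferase of the MYST family whose decline with age the study's title names, is depleted. Kat6b itself (ENSMUSG00000021767, chromosome 14, 21481434 to 21672478, plus strand, GRCm38) had 679, 811 and 531 counts in NTC replicates 1 to 3 and 383, 418 and 443 counts in Kat6b shRNA replicates 1 to 3. After scaling, these were 36.8, 41.4 and 28.9 CPM (counts scaled to library size) with NTC and 31.9, 26.1 and 26.9 CPM with the hairpin. The means were 35.7 ± 6.32 and 28.3 ± 3.16 CPM (SD, n = 3), a log2 fold change of −0.34 (SE 0.19, 95% interval −0.75 to 0.075). In linear terms the Kat6b level with the hairpin was 0.792 of that with NTC, with an interval from 0.596 to 1.05. The groups overlapped, since Kat6b shRNA replicate 1 lay above NTC replicate 3, and the difference did not pass the test (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.954). The level of the Kat6b mRNA therefore does not serve as a check of the labels.

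6 of 13612 tested genes fell with the hairpin and 0 rose. Cd164, which encodes the sialomucin endolyn, fell the furthest of the 5 called genes with mean CPM of at least 5, from 177 ± 25.2 to 65.9 ± 6.31 CPM, or 2.69-fold (log2 fold change −1.43, SE 0.16, adjusted p = 0.0026). Maf1, a repressor of RNA polymerase III, fell 2.31-fold from 34.0 ± 3.69 to 14.7 ± 0.399 CPM. Rab1a, a GTPase of transport from the endoplasmic reticulum to the Golgi, fell 2.2-fold from 189 ± 8.89 to 85.9 ± 20.1 CPM. Banf1, a chromatin-binding protein of the nuclear envelope, fell 2.16-fold from 130 ± 17 to 60.1 ± 3.58 CPM (adjusted p = 0.018). Scd2, a fatty acid desaturase, fell 1.95-fold from 324 ± 33.2 to 166 ± 10.8 CPM. The sixth gene was S100a9, an alarmin abundant in neutrophils, with 37, 40 and 89 counts in the NTC libraries and 0 in each Kat6b shRNA library. That is at least 43.6-fold lower against a floor of 3 counts over the group, and at least 27.5-fold with any 1 library left out. The adjusted p was 0.03 for Maf1, Rab1a, Scd2 and S100a9 (SD, n = 3 throughout). At an unadjusted p under 0.05 there were 388 lower and 297 higher genes, together 685, where 680.6 would fall under it by chance. DESeq2 called 17 lower and 3 higher genes, the latter being Gzmb, Pld4 and the pseudogene Gm11353, of which the last 2 were named after their values were seen. Of the 6 genes, non-robust dispersions and the replicate block each kept only Banf1 and Cd164, and limma-voom kept all but Maf1. The number called also rested on single libraries. It was 0 without NTC replicate 1, NTC replicate 3 or Kat6b shRNA replicate 2, and 1, Cd164, without NTC replicate 2. It was 8 lower genes without Kat6b shRNA replicate 1, and 10 lower and 2 higher without Kat6b shRNA replicate 3.

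**Figure D1:**
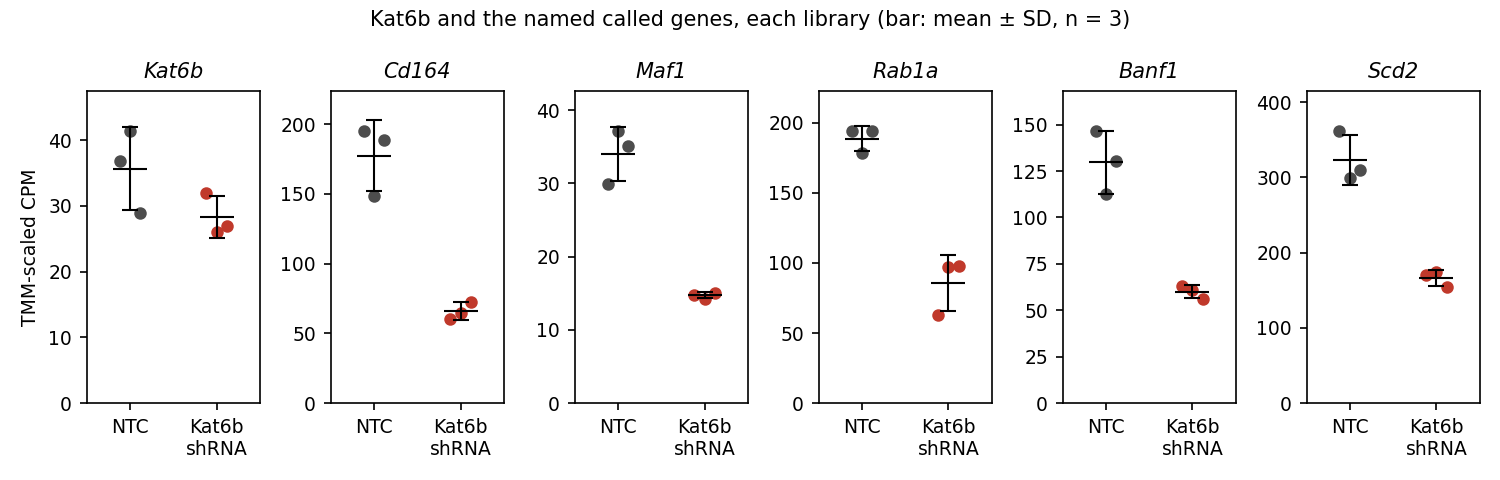
TMM-scaled CPM (vertical axes, starting at 0) of Kat6b and the 5 called genes with a mean of at least 5 CPM, with 1 point per library, a long bar for the mean and whiskers for the SD over 3 libraries per group. The Kat6b points of the groups overlap, whereas each called gene is lower in all 3 Kat6b shRNA libraries than in any NTC library.

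All 5 genes of the plot carry the heptamer GTTTCCA in their annotated 3' UTR, against 15.76% of the 11951 tested genes with such a UTR, and S100a9 does not. By position in GRCm38, Cd164 (ENSMUSG00000019818) spans 41519414 to 41531048 of chromosome 10, and Maf1 (ENSMUSG00000022553) spans 76351294 to 76354380 of chromosome 15. Rab1a (ENSMUSG00000020149) lies at 20201432 to 20226856 of chromosome 11. Banf1 (ENSMUSG00000024844) and Scd2 (ENSMUSG00000025203) lie on chromosome 19, at 5364638 to 5367168 and 44293674 to 44306864. S100a9 (ENSMUSG00000056071) occupies 90692632 to 90695721 of chromosome 3. Over all genes with an annotated 3' UTR, those with the 8 bases GTTTCCAA there had a median log2 fold change of −0.086 (501 genes). The median was −0.03 for 1382 genes with GTTTCCA not followed by A, 0.0081 for 1311 genes with TTTCCAA alone and 0.013 for 8757 genes with neither. At an unadjusted p under 0.05, 9.78% of the GTTTCCAA genes were lower and 1% higher, against 2.64% and 2.1% of the genes with neither. The heptamer was picked from the data.

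**Figure D2:**
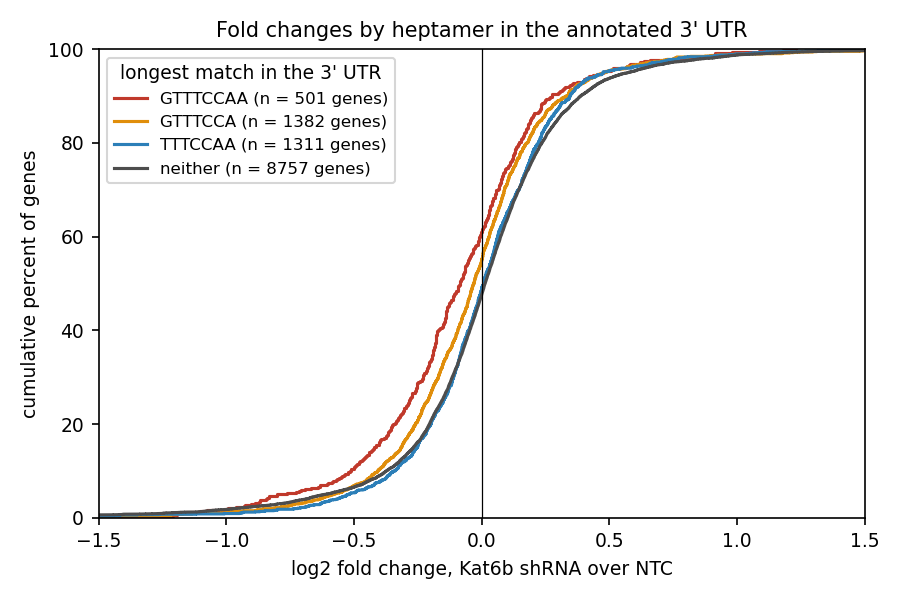
Cumulative percent of genes (vertical axis) against log2 fold change, Kat6b shRNA over NTC (horizontal axis, shown from −1.5 to 1.5), for tested genes with an annotated 3' UTR, by the longest match it holds. The curve of the 501 GTTTCCAA genes lies to the left of that of the 8757 genes with neither, with medians of −0.086 and 0.013.

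Genes that did not pass the adjusted test in edgeR are given as values. DESeq2 called Gzmb and the 7 lower genes that follow. Besides the 5 called ones, the lower genes with the smallest p were Gatm, an enzyme of creatine synthesis (36.0 ± 2.22 against 15.7 ± 3.54 CPM, log2 fold change −1.19, SE 0.21, adjusted p = 0.072), and Nelfcd, a subunit of the negative elongation factor (log2 fold change −1.10, SE 0.20, adjusted p = 0.074). Def8, Myl6b, Ly6a, the tetraspanin gene Cd53 and Rtf1 followed, with log2 fold changes of −0.99, −1.40, −0.86, −1.06 and −0.67 and adjusted p from 0.142 to 0.365. Of these 12 lower genes, 9 carry GTTTCCA in the 3' UTR, and Ly6a, Cd53 and Myl6b do not. On the higher side, Gzmb, the protease granzyme B, had 3.68 ± 1.21 CPM with NTC and 11.4 ± 1.49 CPM with the hairpin (log2 fold change 1.63, SE 0.34, adjusted p = 0.207). Timp3, an inhibitor of metalloproteinases, had 38.0 ± 4.00 and 59.8 ± 7.89 CPM (log2 fold change 0.66, SE 0.17, adjusted p = 0.508). Itga2b, the integrin CD41 of megakaryocytes and platelets, had 67.2 ± 5.25 and 110 ± 33.6 CPM (log2 fold change 0.71, SE 0.19, adjusted p = 0.609), and DESeq2 did not call it. Megf11, Rab11fip2, Rbpms2, Pdss1, Tasp1, Usp40, Slc22a15, Tmcc1 and Nanog had log2 fold changes from 0.51 (Usp40) to 1.52 (Nanog) and adjusted p from 0.827 to 0.872. Nanog is uncertain, because pseudogene copies can share its reads. Of the 12 higher genes only Itga2b carries GTTTCCA.

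Genes of stem cell identity were lower as a group only with a preset correlation. Of 22 tested members, 16 had a negative log2 fold change, the median was −0.23, and the list fell against all other genes (limma camera with a preset correlation of 0.01, adjusted p = 0.01 over 24 lists). With an estimated correlation, which was −0.018 for these genes, camera gave an unadjusted p of 0.021 and an adjusted p of 0.346. That estimate lies below the preset 0.01, so the larger p does not come from a higher correlation among the members. The fry test, which sets a list against no change and not against the other genes, gave an adjusted p of 0.105. Over all genes 0 members passed in edgeR, 6 had an unadjusted p under 0.05, and DESeq2 called Ly6a. When adjusted over the list alone, 3 fell. These were Ly6a, which encodes the stem cell surface antigen Sca-1 (108 ± 15.3 against 59.6 ± 13.7 CPM), Hlf, a transcription factor of stem cells (333 ± 25.1 against 233 ± 24.2 CPM, log2 fold change −0.51), and Robo4, a receptor of the HSC surface named after its value was seen (17.4 ± 3.59 against 9.98 ± 1.71 CPM, log2 fold change −0.80). Kit and Runx1, also picked after their values were seen, had log2 fold changes of 0.036 and 0.026, and Slamf1 had 0.65. Only 3 of the 22 members carry GTTTCCA in the 3' UTR, with a median of −0.23 against −0.24 for the other 19. Without NTC replicate 2 the median was −0.09 and the adjusted p 0.133, and without Kat6b shRNA replicate 1 they were −0.15 and 0.07.

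Myeloid genes were also lower as a group by camera with the preset correlation (15 tested members, 8 negative and 7 positive, median −0.42, adjusted p = 0.017), and the call rested on 2 members. With an estimated correlation the adjusted p was 0.346, and fry, against no change, gave 0.151. S100a9 was called, and S100a8, its partner in calprotectin, had 15, 35 and 77 counts with NTC and 0 in each Kat6b shRNA library, at least 33.4-fold lower (adjusted p = 0.074), and at least 19.5-fold without NTC replicate 3. Of the neutrophil markers fixed beforehand, the 13 left without S100a8, S100a9, Lyz2 and Cxcr2, a subset picked after the values were seen, had 276 counts with NTC, 233 of them in NTC replicate 3, and 30 with the hairpin. Both fell when adjusted over the list alone, as did Spi1, the transcription factor PU.1 (41.7 ± 6.43 against 25.6 ± 7.89 CPM, log2 fold change −0.70). Without S100a8 and S100a9 the adjusted p of the list was 0.434. The median did not depend on the values fitted for them, since both lie below it, but it was 0.12 over the 8 members with at least 1 CPM in every library. Of 2 members picked after their values were seen, Lyz2, the lysozyme of myeloid cells, had 41.7 ± 7.74 CPM with NTC and 43.7 ± 10.2 CPM with the hairpin, and the cytokine receptor gene Csf2ra had 17.4 ± 2.2 and 26.5 ± 10.1 CPM. Without NTC replicate 2 the median was −0.11 and the adjusted p 0.133, and without Kat6b shRNA replicate 1 they were −0.44 and 0.098.

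No other lineage passed the test. Megakaryocyte genes had a median of 0.19 over 18 members (adjusted p = 0.064), and Itga2b rose when adjusted over the list alone. Over the left-out libraries its median ranged from 0.093 to 0.27, and it was called only without NTC replicate 3, with an adjusted p of 0.022. Cd9, the other member named, had 133 ± 23.1 and 174 ± 43.7 CPM. Lymphoid genes had a median of −0.076 over 11 members (adjusted p = 0.325), with Ikzf1 at 250 ± 14.3 and 194 ± 36.8 CPM and Sell at a log2 fold change of 0.88 (SE 0.58). With no filter on low counts the lymphoid median was 0.155 over 19 members. Erythroid genes had a median of −0.017 over 10 members (adjusted p = 0.62), with Hbb-bt at 131 ± 30.1 and 95.5 ± 12.2 CPM and Tfrc at 69.0 ± 5.01 and 84.3 ± 7.51 CPM. Hbb-bt is uncertain because near-identical globin genes can share its reads. Of the markers of other cells that a stem cell sort could carry along, few were expressed enough to be tested. The mast cell and basophil list had 4 tested members, too few for the list test, where Gzmb rose when adjusted over the list alone and Cpa3 had 1.42 ± 0.905 and 0.464 ± 0.482 CPM. The macrophage list had 3, all negative, and was called with no filter on low counts (median −1.36 over 6 members). Among the 3 were Axl at 7.18 ± 2.23 and 3.19 ± 2.05 CPM and Cd68 at 17.3 ± 2.2 and 14.7 ± 2.13 CPM. Of the mature T and NK cell list only Nkg7 was tested, at 10.5 ± 2.12 and 8.98 ± 2.09 CPM. Stromal and endothelial genes had a median of 0.00048 and a mean of −0.082 over 6 members (adjusted p = 0.694), with log2 fold changes of −0.27 for Col1a2 and −0.19 for Emcn, the latter 0.045 without NTC replicate 1.

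Transcripts of the mitochondrial genome were higher as a group with the preset correlation, a call that was lost without either of 2 libraries. All 13 protein-coding genes had positive log2 fold changes, with a median of 0.35, and the list rose by camera (adjusted p = 0.0082). With an estimated correlation, which was 0.893 for these genes, the adjusted p was 0.792, and fry, against no change, gave 0.81. In edgeR 0 members passed over all genes or when adjusted over the list alone, 0 were called by DESeq2 and 3 had an unadjusted p under 0.05. mt-Co1, a subunit of cytochrome c oxidase, had 14155 ± 1737 and 21242 ± 4811 CPM (log2 fold change 0.59), and mt-Nd1, a subunit of complex I, had 3208 ± 295.0 and 4514 ± 1082 CPM. Mitochondrial protein-coding genes took 5.78% of the counts in Kat6b shRNA replicate 1 and 4.32% and 4.31% in replicates 2 and 3, against 3.2% to 3.98% with NTC (exact two-sided permutation test, p = 0.1, the smallest possible). In the same exact two-sided permutation test the share of all mitochondrial genes gave p = 0.3 and that of mitochondrial rRNA p = 0.4, with Kat6b shRNA replicate 3 (16.1% rRNA) below every NTC library. Without Kat6b shRNA replicate 1 the median was 0.074 and the adjusted p 0.37, and without NTC replicate 2 they were 0.23 and 0.237. The median was larger without Kat6b shRNA replicate 3 (0.58) and without NTC replicate 3 (0.49). Nuclear genes of oxidative phosphorylation had a median of 0.097 over 58 members (adjusted p = 0.255), with Ndufb9 at 32.5 ± 6.35 and 46.5 ± 9.97 CPM and Cox7b at 105 ± 3.73 and 147 ± 54.1 CPM. Ribosomal protein genes had a median of 0.10 over 74 members (adjusted p = 0.27), with Rpl12 and Rps18 at log2 fold changes of 0.35 and 0.32.

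**Figure D3:**
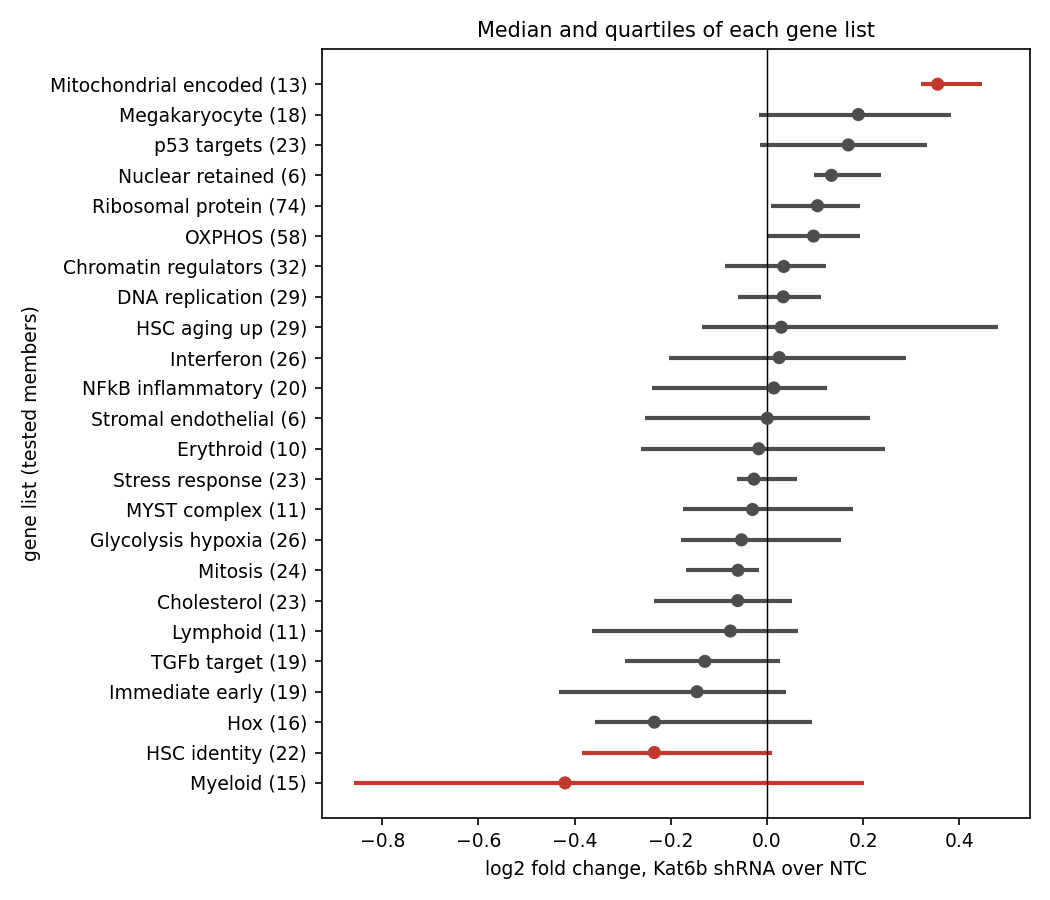
Median log2 fold change, Kat6b shRNA over NTC (horizontal axis), of each gene list with at least 5 tested members (vertical axis, number of members in parentheses), with a line from the lower to the upper quartile of its members. Red marks the 3 lists called with a preset correlation, namely mitochondrial encoded (0.35), HSC identity (−0.23) and myeloid (−0.42), none of which was called with an estimated correlation.

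The MYST complex list, with Kat6b, its paralogue Kat6a and their partners, had a median of −0.03 over 11 members (adjusted p = 0.694), and Kat5 had 14.2 ± 3.73 and 11.4 ± 0.987 CPM. Other chromatin regulators had a median of 0.035 over 32 members (adjusted p = 0.714), with Ezh1, a methyltransferase of Polycomb complex 2, at 32.5 ± 5.19 and 21.7 ± 4.09 CPM and the DNA methyltransferase Dnmt3b at 218 ± 17.5 and 278 ± 36.6 CPM. Hox genes and their cofactors had a median of −0.23 over 16 members (adjusted p = 0.246, median from −0.24 to −0.12 over the left-out libraries), with log2 fold changes of −0.49 for Hoxa7 and −0.81 for Hoxb5. Genes higher in aged HSCs had a median of 0.03 over 29 members (adjusted p = 0.486), with Slamf1 at 16.3 ± 0.505 and 25.6 ± 8.91 CPM and Clca3a1 at 12.7 ± 0.0597 and 18.6 ± 2.80 CPM. The TGF-beta list had a median of −0.13 over 19 members (adjusted p = 0.086, median from −0.15 to −0.042 over the left-out libraries), with log2 fold changes of −0.72 for the inhibitory Smad7 and −0.40 for Tgfbr3.

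Immediate early genes had a median of −0.15 over 19 members (adjusted p = 0.086, median from −0.29 to −0.081 over the left-out libraries), and 1 of them, Fosl2, fell when adjusted over the list alone (18.5 ± 3.41 against 8.56 ± 2.76 CPM, log2 fold change −1.12), while Jun had a log2 fold change of −0.55. The immediate early and TGF-beta lists were both called without Kat6b shRNA replicate 2. p53 targets had a median of 0.17 over 23 members (adjusted p = 0.069), with Ccng1 at 168 ± 5.67 and 209 ± 36.3 CPM and Zmat3 at 110 ± 10.7 and 138 ± 24 CPM. Interferon-response genes, which viral infection can induce, had a median of 0.025 over 26 members (adjusted p = 0.515), with Usp18 and Xaf1 at log2 fold changes of 0.92 and 0.56. NF-kB and inflammatory genes had a median of 0.014 and a mean of −0.031 over 20 members (adjusted p = 0.694), with log2 fold changes of 0.66 for Birc3 and −0.30 for Sod2. Mitosis genes had a median of −0.06 over 24 members (adjusted p = 0.297), with log2 fold changes of −0.30 for Aurka and −0.19 for Cdc20. DNA replication genes had a median of 0.034 over 29 members (adjusted p = 0.649), with Ccne2 and Gins2 at 0.49 and 0.29. Mitosis, ribosomal protein and oxidative phosphorylation lists were called without Kat6b shRNA replicate 3, and without Kat6b shRNA replicate 1 their medians changed sign, to 0.086, −0.098 and −0.012.

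Cholesterol synthesis genes had a median of −0.061 over 23 members (adjusted p = 0.297), with Dhcr7 at 45.1 ± 13.9 and 29.9 ± 3.04 CPM and Dhcr24 at a log2 fold change of −0.31. Genes of glycolysis and hypoxia had a median of −0.053 over 26 members (adjusted p = 0.62), with log2 fold changes of 0.43 for the glucose transporter Slc2a3 and −0.40 for the phosphofructokinase Pfkl. Stress-response genes had a median of −0.027 and a mean of 0.0097 over 23 members (adjusted p = 0.932), with log2 fold changes of −0.45 for Pdia4 and 0.50 for Dnajb9. Nuclear-retained RNAs had a median of 0.13 and a mean of −0.031 over 6 members, and the camera test, which pointed down, gave an adjusted p of 0.507. Among them Meg3 had 2.29 ± 0.404 and 1.04 ± 0.365 CPM and Rian 6.93 ± 1.89 and 8.34 ± 3.32 CPM. Without Kat6b shRNA replicate 1 that list was called (adjusted p = 0.049) and the log2 fold change of Rian was −0.068 in place of 0.26. In the lists from the MYST complex to the nuclear-retained RNAs, Fosl2 was the only member to pass when adjusted over the list alone, and no member was among the 6 genes called by edgeR or the 20 called by DESeq2.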

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

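The alternatives without mitochondrial and rRNA-like genes and without genes with a GTTTCCA or TTTCCAA site were chosen after the data were seen. The Kat6b log2 fold change stayed negative and short of the threshold in all 16 alternatives run for it, from −0.47 to −0.22, with adjusted p from 0.709 to 0.9998. The count of lower genes was 17 with DESeq2, 13 with no filter, 2 with non-robust dispersions and 0 without genes with a GTTTCCA or TTTCCAA site. It ranged from 0 to 10 when 1 library was left out. The count of higher genes was 3 with DESeq2 and 4 with no filter, and ranged from 0 to 2 when 1 library was left out. DESeq2, no filter, RLE factors, upper-quartile factors and 10 counts in 3 libraries each included the 6 genes called in the report. Banf1 and Cd164 were the 2 that non-robust dispersions called. The 6 folds kept their direction in every alternative that tested them, for Cd164 from −1.54 to −1.36 without 1 library and from −1.43 to −1.42 in the others. S100a9 was not tested with 1 CPM in 6 libraries, which leaves out genes at 0 in a library. Fits without a library have fewer samples. The fit without heptamer sites leaves out the 5 other called genes by construction, and S100a9 then misses the threshold. Over all 72 named genes, 1095 of 1147 values kept direction and side of the threshold, 32 lost a call and 18 gained one. Emcn reversed without NTC replicate 1 (0.045, range −0.40 to 0.045 over the left-out libraries), and Rian reversed without Kat6b shRNA replicate 1 (−0.068, range −0.068 to 0.51). For these, and for the counts with DESeq2, no filter and non-robust dispersions, the cause was not tested.

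The count of gene lists called was 0 with an estimated correlation, 0 with fry, which asks a different question (each list against no change), and 4 with no filter, where the macrophage list was added. It ranged from 0 to 6 when 1 library was left out, and the medians of 12 of the 24 lists took both signs over these fits. In either direction, fry's mixed test gave adjusted p of 0.012 for HSC identity and 0.0021 for the myeloid list. Column names carry BR1, BR2 and BR4 for replicates 1, 2 and 3 of both groups. No label says what equal numbers share. Correlations of the deviations of same-number libraries were 0.027, 0.069 and −0.012. These low values do not show pairing, but with 3 libraries per group they cannot exclude it. With the replicate block 2 genes were lower, Banf1 and Cd164, and 1 was higher, the predicted gene Gm13394, while the 3 lists stayed called and Kat6b stood at −0.33. No library correlated with the one of its own number at more than 0.1. NTC replicates 1 and 2 each correlated best with the Kat6b shRNA library of their own number, and NTC replicate 3 with Kat6b shRNA replicate 1.

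Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 6 lower genes and the highest other 1, so only the real split had as many. For higher genes the real split gave 0 and the highest other 1. All 10 splits have at least 0 by definition, so this part of the check decides nothing. For gene lists the real split gave 3, the highest other 6, and 7 splits, the real one among them, had at least 3. The splits are too few for a share under 0.05. Depth limits the low genes: S100a8 and S100a9 had at most 77 and 89 counts in a library, and a level below 0.0674 CPM was not detectable over the Kat6b shRNA group.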

Other observations

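The tests on the loss of Kat6b itself and on the library Kat6b shRNA replicate 1, and the fit without genes that carry a heptamer site, were chosen after the results were seen. 4 genes had no count in any library of 1 group and at least 10 counts in every library of the other. Kcnj5, a potassium channel gene (chromosome 9, 32314707 to 32344350), had 11, 14 and 16 counts with NTC and 0 with the hairpin. The neighbours S100a8 and S100a9 on chromosome 3 were the other 2 seen with NTC alone. The pseudogene Gm11353 (chromosome 13, 26492554 to 26493180) had 13, 11 and 25 counts with the hairpin and 0 with NTC. In the other choices of 3 libraries between 0 and 2 genes were at 0 in those 3 alone. Over all tested genes, the groups did not overlap for 10.5%, where chance gives 10%.

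The stem cell identity and myeloid lists did not follow the heptamer GTTTCCA. Of the 15 tested myeloid genes 0 carry it in the 3' UTR. Without the 3194 genes that carry GTTTCCA or TTTCCAA, stem cell identity (18 members left, adjusted p = 0.006), myeloid (adjusted p = 0.015) and mitochondrial genes (adjusted p = 0.006) were each still called by camera with the preset correlation. Of the mitochondrial members 0 had a 3' UTR to search. For the mitochondrial and myeloid lists the result was thus nearly fixed in advance and decides little. With all genes tested, none of the 3 was called with an estimated correlation (adjusted p = 0.346, 0.346 and 0.792), and that was not tried without the carriers.

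The pattern a biologist may most want to follow up is that the genes called lower share a short sequence. Of 16119 heptamers, GTTTCCA in the 3' UTR went with the lowest fold changes (t = −12.2, against −5.03 for the lowest heptamer in any of 100 permutations), followed by TTTCCAA (t = −7.93), which overlaps it by 6 bases, while the highest t was 5.72. A candidate explanation, written down before the search, is an off-target effect of the Kat6b hairpin, whose seed would pair with this sequence as a microRNA does. Values in line with it are that 5 of the 6 called genes carry the heptamer, and that leaving out any library kept it first, with t from −12.4 to −10.0, although it was picked on these same libraries. From single NTC to single Kat6b shRNA libraries, the median shift of its carriers was set against that of genes with neither heptamer. The difference was −0.13 to −0.018 log2, negative in 9 of 9 pairs, which reuse the same 6 libraries and so are not independent. Between libraries of 1 group it was −0.067 to 0.046, with a sign set only by library order, so the sizes overlap. On base composition, each t was fitted with the dinucleotide composition and length of the UTR as covariates, which take out their linear effect beforehand. In that fit 419 other heptamers of the same bases in the 3' UTR had a median t of −0.12, from −4.79 to 2.90. A median near 0 was thus likely in any case and decides little. The 1134 genes with GTTTCCA in coding sequence but not in the 3' UTR had a median log2 fold change of 0.0038. Over all 1365 genes with it in coding sequence t was −3.76, but these include 3' UTR carriers and the covariates were those of the UTR. What stays open is a part for the loss of Kat6b itself: without carriers of either heptamer edgeR called 0 genes (479 of 10418 at an unadjusted p under 0.05), which a small loss of Kat6b would also give, DESeq2 on all genes called 7 with an annotated 3' UTR that holds neither, among them Ly6a, Cd53 and Myl6b, and with 1 hairpin the 2 cannot be told apart.

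The hairpin's sequence was not used here. The longest annotated Kat6b mRNA (7699 bases) holds 1 copy of GTTTCCA, from base 3242 and outside the 3' UTR, as a hairpin with that seed would need, but 33.2% of the heptamers searched occur in that mRNA. Carriers of 1 copy had a median log2 fold change of −0.03 (1590 genes), of 2 copies −0.093 (243 genes) and of 3 or more −0.068 (50 genes), so the fold did not keep growing with copies. Permuting over genes sets too narrow a bound. In splits of the libraries that mix the groups, ATCCGCC reached t = −5.32 and GGGATTA t = −5.47, beyond the −5.03 of the permutations. GTTTCCA ranked first in 3 of these splits as well, with t = −6.09, −4.81 and 6.01. That does not count against the pattern, because each side of a mixed split holds 2 libraries of 1 group. Part of the group difference therefore stays in it, and carriers were lower on the side with 2 Kat6b shRNA libraries in every mixed split. The 10 splits are too few for a share under 0.05.

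S100a8 and S100a9 at 0 in all 3 Kat6b shRNA libraries might reflect traces of neutrophil RNA in the NTC libraries, which the isolation of LT-HSCs before infection should remove. The summed CPM of 15 other neutrophil markers fixed beforehand was not higher with NTC (0.792 of that with the hairpin). That value decides little, because Lyz2 and Cxcr2, abundant in every library of both groups, gave 96.5% of those counts and would hide a small share. Which cells their counts came from was not tested. The remaining 13 markers had 35, 8 and 233 counts in NTC replicates 1 to 3 and 6, 15 and 9 with the hairpin, and Ngp had 100 in NTC replicate 3 and 0 or 1 elsewhere. In NTC replicate 2 the 8 counts of these markers lie within the range of the hairpin libraries, although S100a9 had 40 counts there, but 1 library decides nothing, and neutrophil RNA and a change within the stem cells cannot be told apart.

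Mitochondrial transcripts higher with the hairpin may come in part from the composition of Kat6b shRNA replicate 1. Without it the median log2 fold change of the 13 genes was 0.074 in place of 0.35, but this library was singled out after the values were seen, and leaving out the highest one lowers the median whatever the cause, so the test decides nothing. This library is also the shallowest and has the largest share of mitochondrial ribosomal RNA, at 26.8% against 16.1% to 19.9% in the other 5. Mitochondrial protein-coding genes took 4.32% and 4.31% of the counts in the other 2 Kat6b shRNA libraries, above the 3.98% of the highest NTC library, so a smaller difference that does not depend on that library stays open.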
